A study of Mus musculus with 16 samples.

How the data were processed

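Gene expression was measured by bulk RNA sequencing in newborn mouse lung on postnatal day 0. Libraries came from whole lung (3 wild-type, WT, and 3 Sfrp1 knockout, KO) and from sorted PDGFRa+ lung cells (5 WT and 5 KO). The labels call the libraries biological replicates, without saying whether animals shared a litter or gave both preparations. Per the labels' protocols, RNA was extracted on silica columns, and both ribosomal RNA depletion with TruSeq chemistry and low-input cDNA synthesis with Nextera XT are described, without tying either to a preparation.

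The values are gene-level TPM (transcript abundances scaled to a fixed library total), as deposited by the authors in 1 table per preparation. The deposited tables are named for kallisto, which assigns reads to transcripts by pseudoalignment. Its version and the transcript annotation are not given in the sources used here, and the genome build is GRCm38 per the submitters' processing notes. A row of the PDGFRa+ table without a gene name held 0.00775% to 0.0287% of each library and was left out. The tables list 35764 genes for whole lung and 35770 for PDGFRa+ cells, with 35420 in both, so genotypes were compared within a table. TPM keeps no sequencing depth, so depth is unknown and no counting interval is given. Genes above 0 numbered 16276 to 20506 in WT and 20819 to 21097 in KO libraries of whole lung, and 14627 to 16482 and 15066 to 17500 in those of PDGFRa+ cells.

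Values were analysed as log2(TPM + 1), and every log2 fold change is on that scale, which understates the change of low genes. Genes with a mean of at least 1 TPM over a table were tested, 16824 in whole lung and 13569 in PDGFRa+ cells. KO was compared with WT with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Every p and adjusted p of a gene is from limma unless an exact test is named. Gene lists were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the 42 of 43 lists with at least 5 tested members. Each list was also tested with a correlation estimated from the data, and with fry, which asks whether members move one way on balance. The limma p of members was also adjusted over their list alone, which leaves error over the 42 lists uncontrolled. The difference between preparations was tested in limma as the interaction of genotype and preparation over the 16 libraries, for 12812 genes tested in both. The lists, main tests and naming rule were fixed before the data were examined.

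By that rule Sfrp1 comes first. Next are genes past the threshold with at least 5 TPM in the higher group, no overlap between WT and KO libraries and a symbol other than a predicted-gene name, at most 8 per direction by fold change. Up to 4 members with the smallest p are named per list described, and 11 preset genes are given in both comparisons. For the difference between preparations, the 5 largest differences per direction are named. Other genes named were chosen after their values were seen. A result for a list in whole lung is not reported here. Gene positions are from GENCODE annotation of GRCm38, matched by symbol. Near-identical copies were sought with BLAST+ 2.17.0 at no less than 95% identity over 50% of a transcript. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

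The procedure was tested on simulated data with 50 genes changed at each size. In the whole lung layout it recovered 0, 20 and 39 of 50 genes changed by 1, 2 and 4 on the log2 scale, in the PDGFRa+ layout 2, 15 and 45, and for the difference between preparations 0, 12 and 34. In the same runs 3, 10 and 4 genes with no simulated change were called.

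Alternatives covered the pseudocount, the filter on low values, scaling between libraries, removal of haemoglobin and mitochondrial genes, robust moderation, array weights, a replicate block, a sex covariate, a separate spread per table and each library left out in turn. The sex covariate was planned as Y-linked genes against Xist. Xist was not used here, so it rests on 4 Y-linked genes. A restriction to protein-coding genes and the joint removal of 2 PDGFRa+ libraries were added after seeing the data.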

Results

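RNA was profiled from newborn lungs of mice with and without Sfrp1, which encodes a secreted Wnt antagonist. The series title ties the gene to distal lung formation through Wnt and PDGF signalling. The comparisons ask how its loss alters whole lung (3 WT and 3 KO libraries) and sorted PDGFRa+ cells (5 WT and 5 KO libraries), a mesenchymal population that includes precursors of myofibroblasts and lipofibroblasts. Levels are TPM as mean ± SD over these libraries, the lowest and highest value where a library was listed at 0, or the values of replicates in order where the SD exceeded the mean.

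Sfrp1 (chromosome 8, 23411502 to 23449632, GRCm38) was lower in every KO library than in any WT library of the same preparation. In whole lung it was 8.64 ± 0.603 TPM in WT and 1.39 ± 0.343 TPM in KO, a log2 fold change of -2.02 (SE 0.37) that missed the threshold over all genes (limma adjusted p = 0.117). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. In PDGFRa+ cells it was 94.2 ± 62.7 TPM in WT and 3.303, 0.09398, 0.217, 1.04 and 1.31 TPM in KO, and the log2 fold change was -5.42 (SE 0.53, limma adjusted p = 0.000257). The exact two-sided permutation p was 0.00794, the smallest that 5 against 5 allow.

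**Figure D1:**
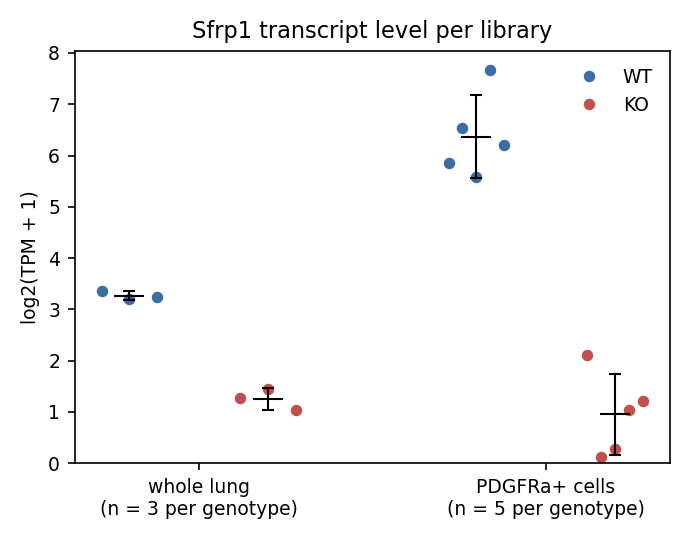
Sfrp1 as log2(TPM + 1) on the vertical axis in each library of both preparations, WT in blue and KO in red, with mean and SD in black. Within each preparation every KO library lies below every WT library.

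In whole lung, striated muscle, inflammatory cytokine and myofibroblast genes stood higher in KO as sets, and replication-dependent histones and lipofibroblast genes lower. None of these list calls held with an estimated correlation (adjusted p from 0.495 to 0.546). With fry, skeletal muscle and myofibroblast genes passed (adjusted p = 0.0237 and 0.0425). Cardiac muscle, inflammatory cytokine, histone and lipofibroblast genes did not (fry adjusted p = 0.0667, 0.106, 0.223 and 0.767). Few single genes passed. Of 16824 genes, 2 passed the threshold with limma, both higher in KO, while 1964 had an unadjusted p under 0.05 (1749 higher, 215 lower). The KO libraries had more genes above 0 (20819 to 21097) than the WT libraries (16276 to 20506), and their top 10 genes took 8.78 to 9.05% of TPM against 11.3 to 14.4%. The tRNA synthetase gene Lars2, chosen after its value was seen, was 3798 ± 1774 TPM in WT and 429 ± 137 TPM in KO (adjusted p = 0.0652, and 0.0468 with array weights, 0.0436 with protein-coding genes only and 0.0176 without WT replicate 2), and no library of one genotype lay within the range of the other in these 3 measures. The called genes, named after their values were seen, are Gm6969 and Gm52957. Gm6969, a processed pseudogene (chromosome 12, 24638669 to 24639010) that matches Cox7a2l at 100% identity over 59% of its length, was 10.9 ± 6.72 TPM in WT and 908 ± 413 TPM in KO (log2 fold change 6.35, adjusted p = 0.0169). Cox7a2l itself was 454 ± 107 TPM in WT and 147 ± 45.5 TPM in KO (adjusted p = 0.115), and reads shared between these genes leave both levels uncertain. Gm52957 was listed at 0 in all 3 WT libraries and at 40.1, 15.8 and 27.9 TPM in KO (adjusted p = 0.0169). The median log2 fold change of all tested genes was 0.29, against 0.04 after median-of-ratios scaling and -0.01 after quantile normalization. The share of higher genes at an unadjusted p under 0.05 went from 89.1% to 59.6% and 52.9%. Camera tests a list relative to the other genes. Fry and the adjustment over the list alone do not, so a shift shared by all genes enters their results. The count of called genes was 0 without a filter on low values, 19 without WT replicate 2, 14 without KO replicate 2, 1 without KO replicate 1 and 1 without KO replicate 3. It was 0 with the replicate block, 11 with array weights and 16 with protein-coding genes only. The call of Gm52957 ended without WT replicate 3, KO replicate 1 or KO replicate 3 (adjusted p = 0.0505, 0.174 and 0.0962), at a mean of at least 5 TPM (adjusted p = 0.06601) and with quantile normalization (adjusted p = 0.0682), and that of Gm6969 without KO replicate 3 (adjusted p = 0.0699). With the replicate block both calls ended (limma adjusted p = 0.118 each).

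Skeletal muscle genes had a median log2 fold change of 4.56 over 11 tested members (adjusted p = 1.12e-15, and adjusted p = 0.495 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 11 rose. Embryonic myosin heavy chain Myh3 was 1.27 ± 1.12 TPM in WT and 37.7 ± 16.9 TPM in KO, the fast troponin Tnnt3 38.3 ± 26.2 and 340.4 ± 48.5, muscle creatine kinase Ckm 19.2 ± 3.02 and 104 ± 44.4 and the myogenic regulator Myog 0 to 0.168 and 5.74 ± 1.65. Cardiac muscle genes had a median of 2.37 over 14 (adjusted p = 3.02e-13, and adjusted p = 0.495 with an estimated correlation), with 0 past the threshold over all genes and 14 rising adjusted over the list alone. Titin (Ttn) was 46.97 ± 30.4 TPM in WT and 347 ± 163 TPM in KO, and the atrial natriuretic peptide gene Nppa 0 to 2.69 TPM in WT and 441, 15.7 and 442 TPM in KO. Over all genes Myh3 and Tnnt3 passed without WT replicate 2 (adjusted p = 0.0255 and 0.00409), with array weights (adjusted p = 0.0321 and 0.0321) and with protein-coding genes only (adjusted p = 0.0436 and 0.0436), and Myh3, Ckm and Nppa without KO replicate 2 (adjusted p = 0.03999, 0.0246 and 0.00375).

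Inflammatory cytokine genes had a median of 1.66 over 21 (adjusted p = 8.39e-07, and adjusted p = 0.546 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 13 rose. Interleukin gene Il1b was 4.12 ± 1.98 TPM in WT and 49.01, 356 and 36.4 TPM in KO, and the neutrophil attractant Cxcl1 0 to 2.87 TPM in WT and 12.9, 113 and 5.73 TPM in KO. Without KO replicate 2 the mean of the list relative to all genes went from 1.48 to 0.89. Myofibroblast genes had a median of 0.91 over 23 (adjusted p = 0.000337, and adjusted p = 0.495 with an estimated correlation), with 0 past the threshold over all genes and 7 rising adjusted over the list alone. Aspn was 93.6 ± 5.32 TPM in WT and 217 ± 16.2 TPM in KO, and smooth muscle myosin Myh11 38.4 ± 6.11 and 94.6 ± 30.4 TPM. Collagens had a median of 0.53 over 24 (adjusted p = 0.0214, and adjusted p = 0.623 with an estimated correlation), and elastic fibre genes of 0.59 over 20 (adjusted p = 0.0304, and adjusted p = 0.623 with an estimated correlation). In both lists 0 genes passed over all genes, and adjusted over the list alone 5 collagens and 6 elastic fibre genes rose, among them Col5a2, Col12a1, Mfap5 and Fbln2. Both list calls ended without WT replicate 2 (adjusted p = 0.349 for collagens and 0.3203 for elastic fibre genes) or KO replicate 1 (adjusted p = 0.196 and 0.114), where the relative mean of collagens went from 0.24 to 0.14 and 0.0826, and that of elastic fibre genes also without KO replicate 3 (adjusted p = 0.0608). With median-of-ratios scaling both ended (adjusted p = 0.0758 and 0.0758), as they did with the replicate block (adjusted p = 0.0575 and 0.0875). With fry neither passed (adjusted p = 0.109 and 0.0667).

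Replication-dependent histones, whose transcripts accompany DNA synthesis, had a median of -0.95 over 17 in whole lung (adjusted p = 1.14e-13, and adjusted p = 0.495 with an estimated correlation). None passed over all genes or adjusted over the list alone, and the linker histone H1f5 was 52.9 ± 25.5 TPM in WT and 19.7 ± 7.15 TPM in KO. Without WT replicate 3 the mean of the list relative to all genes went from -1.07 to -0.42. Lipofibroblast genes had a median of -0.13 over 26 (adjusted p = 0.001896, and adjusted p = 0.495 with an estimated correlation), again with 0 passing either way. The list was tested relative to all genes, whose median was 0.29, and 12 of its genes were higher and 14 lower in KO. Their relative mean went from -0.42 to -0.28 without WT replicate 1 and -0.63 without WT replicate 2, and the call ended with quantile normalization (adjusted p = 0.107). The lung mesenchyme regulator Tcf21 was 158 ± 40.5 TPM in WT and 82.6 ± 9.54 TPM in KO.

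**Figure D2:**
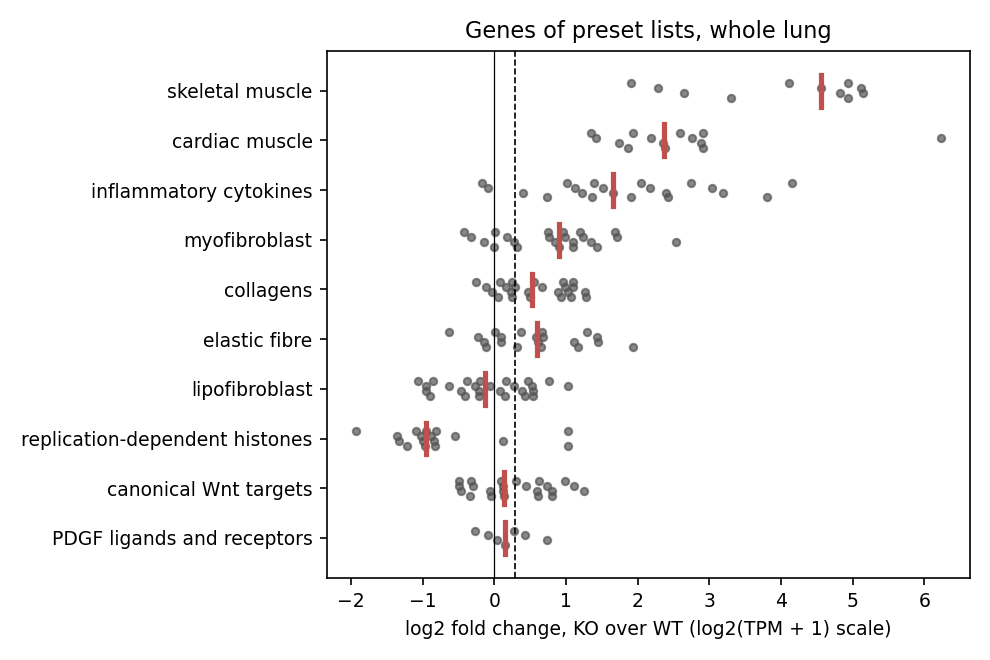
Log2 fold change of KO over WT in whole lung (horizontal axis) for members of 10 preset lists (vertical axis), 1 point per gene, with the list median in red, 0 as a solid line and the median of all tested genes as a dashed line. Skeletal muscle genes have a median of 4.56 and PDGF ligands and receptors of 0.15.

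The Wnt and PDGF lists did not pass in whole lung. Canonical Wnt targets had a median log2 fold change of 0.14 over 23 members (adjusted p = 0.703) and Wnt ligands of 0.33 over 10 (adjusted p = 0.934). Wnt receptors had a median of 0.43 over 21 (adjusted p = 0.354), secreted Wnt antagonists of 0.60 over 11 (adjusted p = 0.268) and PDGF ligands and receptors of 0.15 over 7 (adjusted p = 0.681). Non-canonical Wnt and planar polarity genes had a median of 0.32 over 20 (adjusted p = 0.676). Adjusted over the list alone, the antagonists Sost and Sfrp2 rose and no gene of the other lists passed; none passed over all genes. The Wnt feedback target Axin2 was 49.8 ± 6.76 TPM in WT and 54.9 ± 8.35 TPM in KO, Lef1 14.01 ± 5.37 and 9.27 ± 1.27, Wnt2 10.9 ± 6.04 and 9.38 ± 5.02 and Wnt5a 9.01 ± 1.06 and 20.5 ± 14.5 TPM. Pdgfra was 66.3 ± 7.33 TPM in WT and 71.9 ± 31.3 TPM in KO, its ligand gene Pdgfa 71.3 ± 15.3 and 86.2 ± 18.5, smooth muscle actin Acta2 168 ± 38.1 and 348 ± 169 and elastin (Eln) 1446 ± 148 and 1382 ± 485 TPM. Fgf10 was 13.997 ± 6.94 TPM in WT and 6.92 ± 1.78 TPM in KO, the surfactant gene Sftpc 9276 ± 2769.9 and 5659 ± 1077 and the alveolar type 1 gene Ager 939 ± 303 and 956 ± 337 TPM. None of these 11 genes passed with limma (adjusted p from 0.389 to 0.984). With median-of-ratios scaling the log2 fold change became negative for Axin2 (-0.14), Pdgfra (-0.24), Pdgfa (-0.00474) and Ager (-0.26), and with quantile normalization that of Eln became 0.24. With no filter on low values the secreted Wnt antagonists passed (adjusted p = 0.0144).

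In PDGFRa+ cells, Sfrp1, 4 globin genes, Slco2b1, Hebp1 and Heyl were lower in KO, and Gapdh and Ppbp were higher. Of 13569 genes, 21 passed with limma, 6 higher and 15 lower in KO, and 1337 had an unadjusted p under 0.05 (409 higher, 928 lower). The higher share of the latter was 30.6%, against 54.02% after median-of-ratios scaling and 46.2% after quantile normalization. Among globins, Hbb-bt was 605 ± 337 TPM in WT and 41.4 ± 23.2 TPM in KO (log2 fold change -3.88, adjusted p = 0.00126), Hba-a2 4169 ± 2156 and 475 ± 156 (adjusted p = 0.00202), Hbb-bs 2402 ± 1079.9 and 299.8 ± 108 (adjusted p = 0.00276) and Hba-a1 1043 ± 558 and 129 ± 46.2 TPM (adjusted p = 0.002701). These globins are close in sequence, so the split between them is uncertain. The organic anion transporter Slco2b1 was 3.31 to 25.7 TPM in WT and listed at 0 in KO except 0.633 TPM in KO replicate 2 (adjusted p = 0.0258). The haem-binding gene Hebp1 was 42.7 ± 13.01 TPM in WT and 4.89 ± 2.32 TPM in KO (log2 fold change -2.95, adjusted p = 0.00791), and Heyl, a Notch target, 59.6 ± 21.3 and 8.2005 ± 6.67 TPM (log2 fold change -2.94, SE 0.48, adjusted p = 0.0226). The platelet chemokine gene Ppbp was listed at 0 in all 5 WT libraries and at 49.996, 11.6, 27.1, 23.7 and 11.6 TPM in KO (adjusted p = 0.001504). The glycolytic enzyme gene Gapdh was 198 ± 67.97 TPM in WT and 849 ± 326 TPM in KO (log2 fold change 2.07, adjusted p = 0.0277). The other 4 rises were Gm10359 and Gm12671, copies of Gapdh with equal values in every library, and Gm3226 and Gm3756, copies of Tuba1b, named after their values were seen. A further copy of Gapdh, Gm13394, was 229 ± 98.1 TPM in WT and 0 to 1.12 TPM in KO. The sum of Gapdh and these 3 copies was 427 ± 109 TPM in WT and 933 ± 347 TPM in KO, so the level of each is uncertain. The count of called genes was 39 without KO replicate 2, where Saa3 alone held 110948 TPM, 13 without WT replicate 2, 13 without KO replicate 4 and 48 with array weights. The call of Slco2b1 ended with no filter on low values, at a mean of at least 5 TPM, without WT replicate 1, 3, 4 or 5 or KO replicate 1, 3, 4 or 5, and without WT replicate 3 and KO replicate 2 together (adjusted p = 0.0539 to 0.0982). That of Gapdh ended with no filter, with the Y-linked covariate, without WT replicate 1, 2 or 3 or KO replicate 3, 4 or 5, and without that pair (adjusted p = 0.0515 to 0.17998). That of Heyl ended with no filter, without WT replicate 1, 2, 3 or 5 or KO replicate 4, and without that pair (adjusted p = 0.0553 to 0.0982). That of Hebp1 ended without WT replicate 2 (adjusted p = 0.0578), that of Hbb-bs with no filter (adjusted p = 0.0524) and that of Gm3756 with no filter, at a mean of at least 5 TPM, with quantile normalization, with the Y-linked covariate and without any 1 library other than KO replicate 2 (adjusted p = 0.0534 to 0.139).

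**Figure D3:**
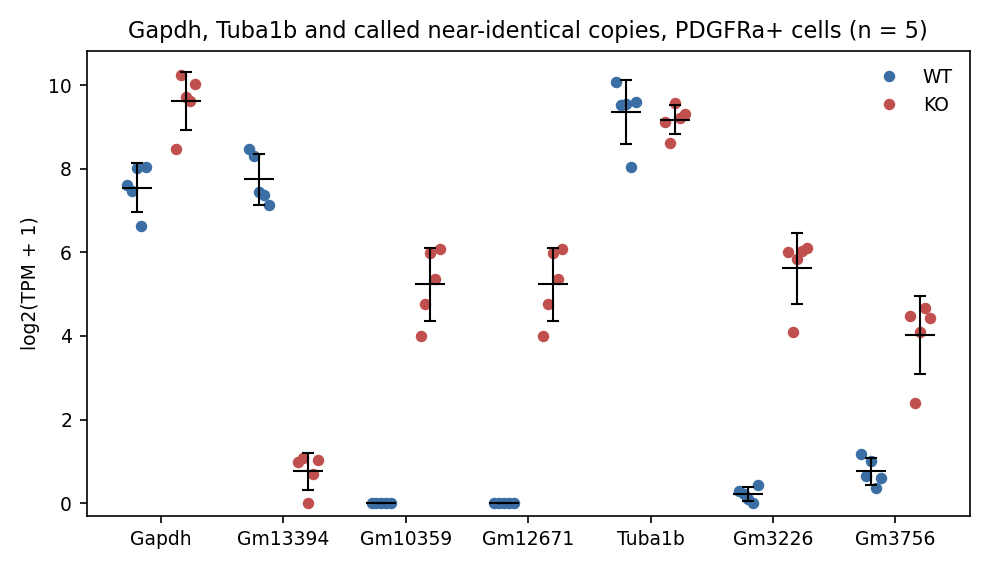
Log2(TPM + 1) on the vertical axis in each PDGFRa+ library for Gapdh, Tuba1b and their called near-identical copies, WT in blue and KO in red, with mean and SD in black (n = 5 each). Gm10359 and Gm12671 are listed at 0 in all WT libraries, and Gm13394 averages 229 TPM in WT and 0.751 TPM in KO.

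Erythroid genes had a median log2 fold change of -2.93 over 7 tested members in PDGFRa+ cells (adjusted p = 4.12e-11), and the 4 globins fell both over all genes and adjusted over the list alone. This list alone among 14 called lists held with an estimated correlation (adjusted p = 0.0158). With fry the erythroid (adjusted p = 0.000515) and hedgehog lists (adjusted p = 0.0105) passed, and no other. Haemoglobin genes took 0.325% to 1.43% of WT libraries and 0.0432% to 0.1301% of KO libraries. Myeloid genes had a median of 0.91 over 12 (adjusted p = 0.00496, and adjusted p = 0.351 with an estimated correlation), and neutrophil and mast cell genes of 0.35 over 13 (adjusted p = 0.00745, and adjusted p = 0.351 with an estimated correlation). Over all genes 0 passed in each, and adjusted over the list alone 3 and 2 rose. In KO replicates 1 to 5 the myeloid adaptor gene Tyrobp was 16.9, 138, 4.65, 13.6 and 9.39 TPM (0 to 2.99 in WT) and the neutrophil gene S100a8 460.3, 10003, 31.01, 239 and 7.92 TPM (0 to 4.42 in WT). Without KO replicate 2 both list calls ended (adjusted p = 0.191 and 0.166), and the means relative to all genes went from 1.14 to 0.69 and from 1.46 to 0.97. They also ended without WT replicate 3 and KO replicate 2 together (adjusted p = 0.226 and 0.231). S100a8 passed over all genes with a pseudocount of 0.1, quantile normalization or the Y-linked covariate, and without KO replicate 2 or KO replicate 5 (adjusted p = 0.0118 to 0.0487).

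In KO PDGFRa+ cells the lipofibroblast, myofibroblast, and pericyte and vascular smooth muscle lists stood lower, and the matrix fibroblast, collagen and elastic fibre lists did not pass. Lipofibroblast genes had a median of -0.55 over 25 (adjusted p = 0.00118, and adjusted p = 0.238 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 10 fell and 1 rose. Inmt was 85.1, 47.7, 657, 984 and 129.5 TPM in WT and 0 to 33.9 TPM in KO, and Tcf21 was 308 ± 127 TPM in WT and 7.77, 30.5, 199.8, 36.9 and 34.9 TPM in KO. Hedgehog genes had a median of -0.78 over 14 (adjusted p = 0.00137, and adjusted p = 0.191 with an estimated correlation), with 0 past the threshold over all genes and 3 falling adjusted over the list alone. The pathway target Gli1 was 39.6 ± 15.5 TPM in WT and 6.66 ± 5.48 TPM in KO, and Foxl1 12.2 ± 5.94 and 0 to 3.35 TPM. Myofibroblast genes had a median of -0.66 over 24 (adjusted p = 0.0107, and adjusted p = 0.384 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 5 fell, among them Tagln (276 ± 168 and 47.7 ± 26.3 TPM in WT and KO), and 2 rose, among them Cdh4 (4.11 ± 2.94 and 17.6 ± 7.8). TGF-beta genes had a median of -0.44 over 20 (adjusted p = 0.0179, and adjusted p = 0.238 with an estimated correlation), and pericyte and vascular smooth muscle genes of -0.61 over 18 (adjusted p = 0.0231, and adjusted p = 0.351 with an estimated correlation). Pmepa1 fell in the former adjusted over the list alone, with 0 genes over all genes, and Heyl fell in the latter both ways. Without WT replicate 5 the calls of the myofibroblast, TGF-beta and pericyte lists ended (adjusted p = 0.0602, 0.0547 and 0.0547), without KO replicate 2 those of the TGF-beta and pericyte lists (adjusted p = 0.1003 and 0.191) and without WT replicate 2 that of the pericyte list (adjusted p = 0.0698). With array weights all 3 ended (adjusted p = 0.0641 each), as they did without WT replicate 3 and KO replicate 2 together (adjusted p = 0.179 each), and at a mean of at least 5 TPM that of the pericyte list ended (adjusted p = 0.128). Over all genes Inmt, Tcf21 and Gli1 passed without KO replicate 3 (adjusted p = 0.0175, 0.00579 and 0.0319) and with the Y-linked covariate (adjusted p = 0.0404, 0.0163 and 0.0392), Tagln and Pmepa1 without WT replicate 4 (adjusted p = 0.0161 and 0.0243), and Tagln, Tcf21 and Gli1 with array weights (adjusted p = 0.0491, 0.04903 and 0.0346). Matrix fibroblast genes had a median of -0.05 over 23 (adjusted p = 0.276), with 11 higher and 12 lower in KO. As a list they passed with a lower mean in KO without KO replicate 1 or 4 (adjusted p = 0.0497 and 0.0289), and with a higher mean without KO replicate 2 (adjusted p = 0.0108) or without WT replicate 3 and KO replicate 2 together (adjusted p = 0.0262). Of these genes Cygb fell over all genes (248 ± 78.3 and 48.8 ± 16.4 TPM in WT and KO). Collagens had a median of -0.14 over 23 (adjusted p = 0.491) and elastic fibre genes of -0.34 over 21 (adjusted p = 0.334).

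Cell cycle genes had a median of 1.18 over 28 in PDGFRa+ cells (adjusted p = 8.63e-11, and adjusted p = 0.351 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 7 rose. Cdc20, an activator of the anaphase-promoting complex, was 49.9, 6.65, 0, 0 and 0 TPM in WT replicates 1 to 5 and 46.2 ± 20.7 TPM in KO, and topoisomerase gene Top2a 26.3, 0.642, 0.343, 0.293 and 0.447 TPM in WT and 26.5 ± 14.6 TPM in KO. Without WT replicate 1 both passed over all genes (adjusted p = 0.01297 and 0.0235). Hypoxia and glycolysis genes had a median of 0.54 over 26 (adjusted p = 9.98e-06, and adjusted p = 0.3002 with an estimated correlation). Gapdh rose over all genes, and Gapdh, Pgam1 and Eno1 rose adjusted over the list alone. The level of Gapdh is uncertain because of its near-identical copies, and its call ended in 9 of 22 settings.

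**Figure D4:**
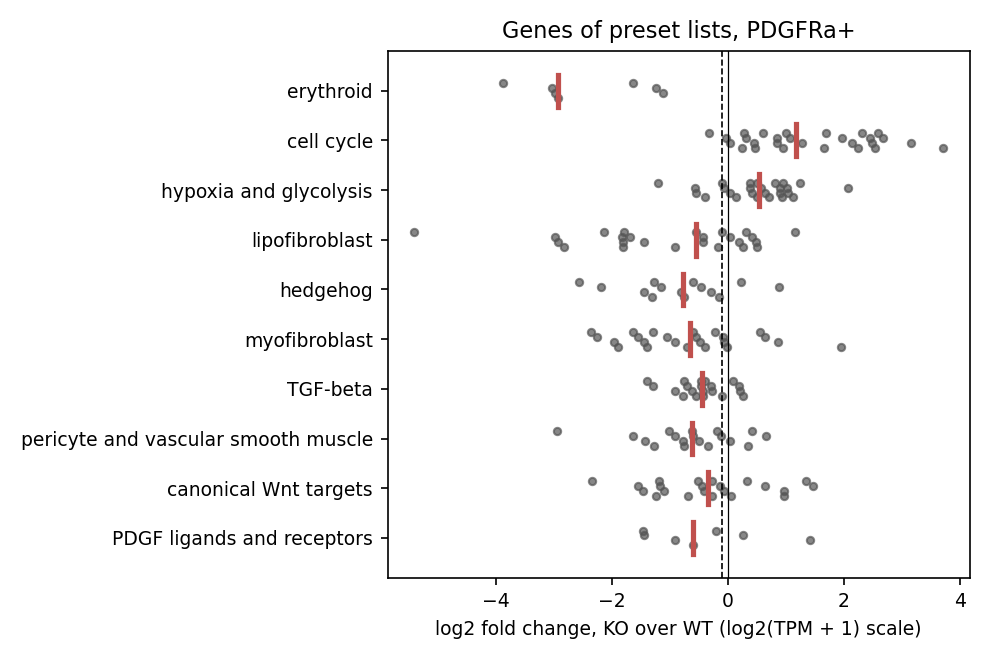
Log2 fold change of KO over WT in PDGFRa+ cells (horizontal axis) for members of 10 preset lists (vertical axis), 1 point per gene, with the list median in red, 0 as a solid line and the median of all tested genes as a dashed line. Erythroid genes have a median of -2.93 and cell cycle genes of 1.18.

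The Wnt and PDGF lists did not pass in PDGFRa+ cells. Canonical Wnt targets had a median log2 fold change of -0.34 over 22 members (adjusted p = 0.334) and Wnt ligands of 0.10 over 11 (adjusted p = 0.662). Wnt receptors had a median of -0.05 over 20 (adjusted p = 0.817), secreted Wnt antagonists of 0.16 over 10 (adjusted p = 0.7904) and PDGF ligands and receptors of -0.60 over 7 (adjusted p = 0.124). Non-canonical Wnt and planar polarity genes had a median of -0.46 over 17 (adjusted p = 0.334). None of their tested genes, which leave out Sfrp1, passed over all genes. Adjusted over the list alone Pdgfrl, Pdgfrb and Pdgfa fell, the Wnt inhibitors Notum and Dkk3 fell, the non-canonical Wnt genes Nfatc4 (86.8 ± 31.95 and 33.3 ± 11.1 TPM in WT and KO) and Dvl1 (68.6 ± 14.5 and 33.3 ± 10.1) fell, and the antagonist Frzb rose. Axin2 was 6.99 ± 4.91 TPM in WT and 2.47 ± 1.77 TPM in KO, Lef1 16.4 ± 13.7 and 14.1 ± 12.3, Wnt2 31.8 ± 7.21 and 51.2 ± 30.9 and Wnt5a 46.96 ± 11.9 and 46.02 ± 17.8 TPM. Pdgfra was 121 ± 32.9 TPM in WT and 104 ± 19.9 TPM in KO, Pdgfa 24.7 ± 12.5 and 8.25 ± 5.45 and Acta2 524 ± 268 and 172 ± 65.4 TPM. Eln was 7947 ± 2109.8 TPM in WT and 2259.6 ± 1338 TPM in KO (log2 fold change -1.98, SE 0.37), and missed the threshold with limma (adjusted p = 0.0534). It passed at a mean of at least 5 TPM, with quantile normalization, robust moderation or the Y-linked covariate, and without KO replicate 2 or KO replicate 3 (adjusted p = 0.0151 to 0.0496). Fgf10 was 10.2 ± 5.398 TPM in WT and 2.98, 1.12, 11.1, 38.6 and 16.5 TPM in KO. Sftpc was 107 ± 98.03 TPM in WT and 6.999, 8.69, 5.14, 84.7 and 587 TPM in KO, and Ager was 13.7, 3.15, 1.33, 5.56 and 1.25 TPM in WT and 0 to 14.5 TPM in KO. The log2 fold change of Wnt5a went from -0.08 to 0.0975 with median-of-ratios scaling, and that of Fgf10 from -0.09 to 0.0477. PDGF ligands and receptors passed as a list, with a lower mean in KO, with no filter on low values (adjusted p = 0.0462) and without WT replicate 3 (adjusted p = 0.0455), and Acta2 passed without WT replicate 4 (adjusted p = 0.01998).

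The KO effect differed between preparations for 6 of 12812 genes (limma interaction), each with a lower change in PDGFRa+ cells. As the log2 change in PDGFRa+ cells minus that in whole lung, the largest differences were Gm6969 (-6.41, adjusted p = 0.0336), Slco2b1 (-4.91, adjusted p = 0.0493), Gli1 (-4.23, adjusted p = 0.0493), Heyl (-4.01, adjusted p = 0.0493) and Mamdc2 (-3.77, adjusted p = 0.0227). The sixth, Cygb (-3.33, adjusted p = 0.01896), was named after its value was seen. The hedgehog target Gli1 had a log2 fold change of 1.67 in whole lung and -2.57 in PDGFRa+ cells, and Heyl of 1.07 and -2.94. Of the settings run, the call ended in 11 of 19 for Gm6969, 18 of 21 for Slco2b1, 18 of 22 each for Gli1 and Heyl and 7 of 22 for Mamdc2. The count was 42 with a separate spread per table and 0 with median-of-ratios scaling. It was also 0 without whole lung WT replicate 3 or any 1 of KO replicates 1, 2 and 3, 1 without whole lung WT replicate 1, 10 without PDGFRa+ WT replicate 4 or KO replicate 2, 3 without PDGFRa+ WT replicate 1, 2, 3 or 5, and 2 without PDGFRa+ KO replicate 1, 4 or 5. No gene was called with limma in both preparations, where 2 and 3 of these genes were called higher and 0 and 14 lower, too few for a test of overlap. At an unadjusted p under 0.05, 53 genes were higher in KO in both (35.8 by chance, one-sided Fisher exact p = 0.00231). Lower in both were 10, Sfrp1 and Tcf21 among them (12.02 by chance, one-sided Fisher exact p = 0.7702). The Fisher test treats genes as independent, which they are not, so its p does not measure agreement over animals. It was run without scaling between libraries only.

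**Figure D5:**
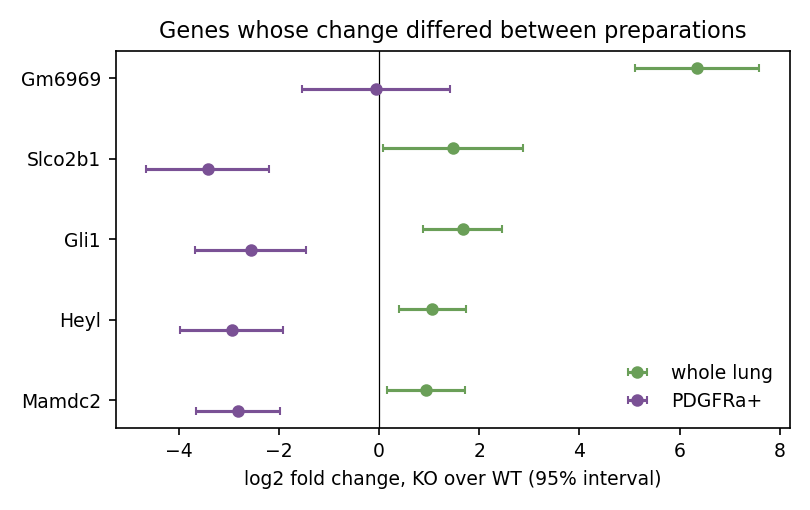
Log2 fold change of KO over WT with its 95% interval (horizontal axis) in whole lung (green) and PDGFRa+ cells (purple) for the 5 genes (vertical axis) with the largest difference between preparations. Gli1 lies at 1.67 in whole lung and -2.57 in PDGFRa+ cells.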

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

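The tests of the spread of muscle genes within KO libraries and of the ratio of 2 globin transcripts were set before their results were seen, and every other test of an explanation here was chosen after.

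Striated muscle transcripts were higher in whole lung KO. A shared upward shift of KO values is argued against, since the skeletal muscle median stayed at 4.32 on the log2 scale after median-of-ratios scaling. Muscle tissue carried into the KO samples at dissection cannot be told apart from a change of muscle gene expression in the KO animals. The largest SD over the skeletal muscle genes of their deviations from the KO means within a KO library was 0.397 on the log2 scale. It met the limit set in advance for carried muscle. It still decides nothing, by a condition that the preset rule did not hold. In every KO library the mean deviation (0.07301, -0.25 and 0.18) was smaller in size than the SD over genes (0.214, 0.397 and 0.358).

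Near-identical copies of Gapdh and Tuba1b separated WT from KO in PDGFRa+ cells. Reads shared between copies stay open. The summed TPM of Gapdh and its 3 called copies changed by 1.06 on the log2 scale, less in size than any of these genes, though the sum was still higher in KO. This decides nothing, because the copies were picked as called genes and moved in opposite directions, which makes the sum change less. The sum of Tuba1b and its 2 called copies changed by -0.0216. The 3 Gapdh copies were listed at 0 in every whole lung library. A sequence variant of the KO animals was left undecided for the Tuba1b copies by Gm3226 in whole lung (0.31, 95% interval -1.58 to 2.20). WT and KO sorted libraries prepared or quantified apart cannot be told apart from genotype, because all 5 called copies part the libraries by genotype and the labels give no batch.

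Haemoglobin transcripts were lower in PDGFRa+ KO. Scaling between libraries is argued against, since the Hba-a2 change stayed at or below -2.85 under both scalings. A fall as large in the lungs as a whole is argued against too: the lowest limit of the 95% intervals of 4 globin genes in whole lung was -1.78, which leaves a smaller fall open. Blood RNA carried through the sort in differing amounts met its preset test, as log2(Hbb-bs/Hba-a2) varied little over the 10 libraries (SD 0.232). This does not favour it, because a single source of both transcripts would hold for other changes in blood too. An effect of genotype on blood in the sorted fraction stays open.

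For chance, the real split of whole lung libraries gave 2 called genes, with 1 at most in the other splits (1 of 10 as large, the real one included), and 16 lists against 14 (1 of 10). These splits are too few for a share under 0.05. The other whole lung splits, which mix the genotypes, still called 3 to 14 lists. In PDGFRa+ cells, 1 of 100 splits gave as many as 21 genes (highest other 4) and 4 of 100 as many as 14 lists (highest other 17), and for the difference between preparations 1 of 100 gave as many as 6 genes (highest other 3). The shares argue against chance for the counts of genes in PDGFRa+ cells and, in the main setting, in the difference between preparations. The latter count was 0 with median-of-ratios scaling and 42 with a separate spread per table. It ranged from 0 to 10 without a single library. For the PDGFRa+ lists the share was under 0.05 as well. Chance is not excluded there, because other splits reached or passed the real count. Those splits called 2 to 17 lists, so camera with the preset correlation also calls lists where the genotypes are mixed.

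By Dixon's ratio of gap to range, taken on log2(TPM + 1) for genes, single PDGFRa+ libraries stood far from the others of their genotype in 18 of 204 groups of values tested, where chance gives 10.2, and 8 of them were in KO replicate 2. The chance count holds for continuous values only. Saa3 was added to the tested genes after its values were seen, so its flag in KO replicate 2 cannot be set against chance. For Slco2b1, Retnlg and S100a8 all other libraries of the genotype were listed at 0, so any value above 0 stood apart by construction. In TPM, KO replicate 2 stood apart for Saa3 (110948, others 41.7 to 109.7), Fzd1 (88.9, others 19.6 to 30.6), Boc (9.35, others 32.6 to 53.1), Gm3226 (16.1, others 56.2 to 67.6), Gm3756 (4.27, others 16.1 to 24.6) and Hbb-bs (111, others 325 to 379.8). It also held 0.633 of Slco2b1, listed at 0 in the others, and its top 10 genes took 23.7% of TPM (others 8.58 to 11.6%). KO replicate 3 stood apart for Sox9 (20.9, others 5.44 to 7.48). WT replicate 4 stood apart for Acta2 (94.5, others 472 to 803), Tgfbi (189, others 764 to 1283), Mbp (2.74, others 0 to 0.0669) and S100a9 (1.26, others 0 to 0.217). WT replicate 1 stood apart for Krt8 (11.1, others 0 to 0.08103) and Top2a (26.3, others 0.293 to 0.642), and WT replicate 3 for Pdgfrl (40.5, others 122 to 182). WT replicate 2 held 6.47 of Retnlg and 4.42 of S100a8, both listed at 0 in the other WT libraries.

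The KO effect differed between preparations by the limma interaction for Gm6969 (-6.41), Slco2b1 (-4.91), Gli1 (-4.23), Heyl (-4.01) and Mamdc2 (-3.77), on the log2 scale.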

How the results depend on the processing

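The restriction to protein-coding genes and the joint removal of PDGFRa+ KO replicate 2 and WT replicate 3 were chosen after seeing the data, and all other alternatives before. Sfrp1 kept its direction and side of the threshold in both preparations under each alternative run. Settings other than leaving out a single library include the joint removal of 2 libraries. Over them, values of named genes kept direction and side in 2093 cases, lost the call in 59, gained it in 26 and changed sign in 20. For lists, taking the direction of the test, these counts were 406, 45, 2 and 13. Leaving out a single library they were 1461, 113, 22 and 20 for genes and 319, 32, 3 and 8 for lists. TPM gives no depth, so what depth limits could not be assessed, and the causes of the changes below were not tested.

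The 2 genes called in whole lung became 0 with no filter, 1 at a mean of at least 5 TPM, 1 with quantile normalization, 11 with array weights, 16 with protein-coding genes only and 1 to 19 without a single library. The 16 whole lung lists became 0 with an estimated correlation. With fry 5 lists passed, among them the myeloid list (fry adjusted p = 0.0111), which is not among the 16 (camera adjusted p = 0.172). The 21 genes called in PDGFRa+ cells became 48 with array weights, 14 with protein-coding genes only, 25 without both doubted libraries and 13 to 39 without a single library. The 14 PDGFRa+ lists became 9 at a mean of at least 5 TPM, 9 without both doubted libraries, 1 with an estimated correlation and 2 with fry. The 6 genes whose change differed between preparations became 3 with a pseudocount of 0.1, 2 at a mean of at least 5 TPM, 0 with median-of-ratios scaling, 3 with the Y-linked covariate, 42 with a separate spread per table and 0 to 10 without a single library. The overlap of 0 genes became 63 at an unadjusted p under 0.05.

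The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered WT and KO libraries correlated at 0.03, 0.23 and 0.24 in whole lung. Each WT library matched its own number best there, so pairing stays open in whole lung. In PDGFRa+ cells they correlated at -0.05, -0.15, 0.07, 0.11 and -0.00626, and only replicates 3 and 4 matched best, which gives little sign of pairing. With the replicate block the called genes were 0 in whole lung, 21 in PDGFRa+ cells and 2 for the difference. Of those in PDGFRa+ cells 14 were also called without the block, and the calls of Slco2b1 (adjusted p = 0.111), Hebp1 (adjusted p = 0.0711), Adamts2 (adjusted p = 0.148), Brf1 (adjusted p = 0.157), Gm3756 (adjusted p = 0.0974), Lgals4 (adjusted p = 0.06805) and Thap3 (adjusted p = 0.0711) ended. It also ended the whole lung calls of collagens (adjusted p = 0.0575) and elastic fibre genes (adjusted p = 0.0875), while Eln, Notum, Tagln, Inmt and S100a8 passed in PDGFRa+ cells (adjusted p = 0.0355, 0.0454, 0.0188, 0.00958 and 0.0181), and the whole lung Wnt ligand list turned at 0.0265.

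Directions also turned as follows, as log2 fold changes, or for lists as the mean relative to all genes, where the test's direction can differ from the sign of that mean. In whole lung, median-of-ratios scaling gave Axin2 -0.14, Pdgfra -0.24, Pdgfa -0.00474 and Ager -0.26. Quantile normalization gave Axin2 -0.0614, Pdgfra -0.17, Eln 0.24, mitochondrial genes 0.0876 and Wnt ligands -0.0797. Array weights gave Wnt2 0.34 and Pdgfra -0.26, and a pseudocount of 0.1 gave Wnt ligands 0.0239. Ager was -0.00162 without haemoglobin and mitochondrial genes and -0.00785 with the Y-linked covariate. In PDGFRa+ cells, median-of-ratios scaling gave Wnt5a 0.0975 and Fgf10 0.0477, and quantile normalization Wnt5a 0.11. Array weights gave Fgf10 0.18, Sftpc 0.92, Ager 0.0824, collagens 0.0209 and canonical Wnt targets 0.0526. The Y-linked covariate gave Wnt5a 0.11 and secreted Wnt antagonists 0.33. A mean of at least 5 TPM gave Wnt ligands -0.0997 and Wnt1 -0.33. Wnt receptors were 0.00875 with no filter, and without both doubted libraries 0.00514, with Fgf10 0.13, matrix fibroblast genes 0.30, collagens 0.16 and elastic fibre genes 0.32.

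Some list means relative to all genes changed sign while the direction of the test held. In whole lung, erythroid genes went from -0.29 to 0.06095 without haemoglobin and mitochondrial genes, Wnt ligands from 0.0265 to -0.0104 with no filter, and non-canonical Wnt genes from 0.0133 to -0.0959 with a pseudocount of 0.1, -0.00321 with median-of-ratios scaling and -0.0239 without WT replicate 2. In PDGFRa+ cells, immediate early and dissociation genes went from -0.25 to 0.00364 without both doubted libraries, elastic fibre genes from -0.10 to 0.0479 with array weights, and Wnt receptors from 0.0588 to -0.00192 with a pseudocount of 0.1, -0.0176 at a mean of at least 5 TPM, -0.007104 without WT replicate 4 and -0.0123 without KO replicate 4.

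Without a single whole lung library the range was -0.0217 to 0.12 for Wnt ligands, -0.57 to 0.22 for Wnt2, -0.29 to 0.30 for Pdgfra, -0.38 to 0.12 for Eln, -0.25 to 0.28 for Ager and -0.71 to 0.16 for Pdgfb. Without a single PDGFRa+ library it was -0.0786 to 0.23 for Wnt ligands, 0.33 to 0.82 for secreted Wnt antagonists, -0.24 to 0.11 for Wnt5a, -0.61 to 0.44 for Fgf10, -0.77 to 0.21 for Ager and -0.11 to 0.95 for Ret. Without KO replicate 2 matrix fibroblast genes were 0.39, collagens 0.0978 and elastic fibre genes 0.26, and without KO replicate 1 matrix fibroblast genes were -0.47.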

Other observations

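The test of the region around Sfrp1 was chosen after seeing the data, and the lists were fixed before. In whole lung, other lists that stood higher in KO by camera, with their median log2 fold change, include cholesterol and fatty acid synthesis (0.54 over 25, adjusted p = 0.0118, and adjusted p = 0.623 with an estimated correlation) and lymphatic endothelium (0.68 over 8, adjusted p = 0.0457, and adjusted p = 0.495 with an estimated correlation). Lists that stood lower were interferon response genes (-0.22 over 26, adjusted p = 1.35e-05, and adjusted p = 0.546 with an estimated correlation), mitochondrial encoded genes (-0.20 over 13, adjusted p = 1.901e-05, and adjusted p = 0.495 with an estimated correlation), cell cycle genes (-0.07 over 28, adjusted p = 0.00109, and adjusted p = 0.623 with an estimated correlation) and endothelial genes (-0.04 over 26, adjusted p = 0.00239, and adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone the interferon-induced gene Rtp4 fell, and no gene of these lists passed over all genes. Erythroid genes stood lower by the test (adjusted p = 0.0358, and adjusted p = 0.623 with an estimated correlation), although their median (0.20) and mean (0.05) over 13 genes were above 0. With fry lymphatic endothelium passed (adjusted p = 0.0162), and the other lists named in this paragraph did not (fry adjusted p from 0.0695 to 0.959). Without single libraries the calls of cholesterol and fatty acid synthesis (WT replicate 2 or KO replicate 3, adjusted p = 0.105 and 0.286), lymphatic endothelium (the same libraries, adjusted p = 0.353 and 0.286), cell cycle genes (WT replicate 3 or KO replicate 3, adjusted p = 0.0571 and 0.0529) and erythroid genes (WT replicate 3, KO replicate 1 or KO replicate 2, adjusted p = 0.477, 0.206 and 0.148) ended. The mean relative to all genes of interferon response genes went from -0.50 to -0.33 without WT replicate 2, that of cholesterol and fatty acid synthesis from 0.18 to 0.27 and 0.0543 without KO replicate 2 or 3, that of lymphatic endothelium from 0.41 to 0.27 without KO replicate 3, and that of erythroid genes from -0.29 to -0.45, -0.0322, -0.15, -0.15 and -0.54 without WT replicate 1, WT replicate 3, KO replicate 1, KO replicate 2 and KO replicate 3. Quantile normalization ended the call of mitochondrial encoded genes and turned their relative mean from -0.57 to 0.0876 (adjusted p = 0.7903). Over the settings run with the preset correlation the calls ended in 3 of 16 for cholesterol and fatty acid synthesis, 8 of 16 for lymphatic endothelium, 2 of 16 for cell cycle genes, 9 of 16 for erythroid genes and 0 of 16 each for interferon response and endothelial genes.

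In PDGFRa+ cells, further lists that stood higher in KO were replication-dependent histones (0.79 over 9, adjusted p = 0.0152, and adjusted p = 0.372 with an estimated correlation), pan-epithelial genes (1.11 over 8, adjusted p = 0.0231, and adjusted p = 0.351 with an estimated correlation) and neural and Schwann genes (1.17 over 5, adjusted p = 0.0231, and adjusted p = 0.238 with an estimated correlation), with 0 genes past the threshold over all genes or adjusted over the list alone. Immediate early and dissociation genes stood lower (-0.43 over 25, adjusted p = 0.0231, and adjusted p = 0.741 with an estimated correlation), and adjusted over the list alone 5 fell, among them Btg2, Junb, Zfp36 and Ier2, with 0 over all genes. Without single libraries the calls of the histones (WT replicate 5, adjusted p = 0.0547), pan-epithelial genes (WT replicate 2, WT replicate 5, KO replicate 2 or KO replicate 3, adjusted p = 0.0546, 0.0698, 0.191 and 0.0687) and immediate early and dissociation genes (WT replicate 4, WT replicate 5 or KO replicate 2, adjusted p = 0.0979, 0.0666 and 0.506) ended. Without KO replicate 2 the mean relative to all genes went from 1.04 to 0.64 for pan-epithelial genes and from -0.25 to -0.0383 for immediate early and dissociation genes. Over the settings run with the preset correlation the calls ended in 3 of 20 for the histones, 10 of 21 for pan-epithelial genes, 4 of 20 for neural and Schwann genes and 7 of 21 for immediate early and dissociation genes.

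Within 5 Mb of Sfrp1 on chromosome 8, 15 of 74 tested genes had an unadjusted p under 0.05 in whole lung (20.3%, against 11.8% elsewhere, Fisher exact p = 0.0303, Benjamini-Hochberg adjusted over both preparations 0.0606). In PDGFRa+ cells it was 7 of 62 (11.3%, against 9.88%, Fisher exact p = 0.669). Across 12812 genes, which are not independent replicates, the log2 fold changes of the preparations correlated at Pearson's r = 0.0364 and Spearman's rho = 0.00978.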
